A study of Oryza sativa with 9 samples.

How the data were processed

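RNA was extracted with TRIzol from 14-day-old seedlings, polyadenylated RNA was selected with oligo(dT) beads and stranded libraries were made with a KAPA kit, per the labels' protocols. The deposited table holds FPKM values (fragments scaled to gene length and library size) per library, per the file headers, with 1 column for each of 6 libraries. It also holds the authors' log2 fold changes and the authors' p-values for overexpression over wild type, per the file headers. The submitters' processing notes name FastQC, cutadapt, HISAT2, SAMtools, featureCounts, DESeq2 and deepTools, without versions or order. Which of these made each column, the genome build, the annotation and the strand setting are not given in the sources used here. Whether the authors' p-values were adjusted is likewise not given, and they were adjusted here by the Benjamini-Hochberg method over the 31263 genes with any read.

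Libraries were grouped by genotype from the labels. Both lanes of a wild-type repeat are represented by 1 column and were counted as 1 replicate. The wild-type columns carry a digit after the cultivar abbreviation whose meaning is not given in the sources used here, and they were assigned to the wild type as a group. Gene identifiers are locus numbers as the table gives them. The reference table of gene symbols holds no such locus numbers, so names come from 22 lists of 242 members fixed before the data were examined. Of these, 240 members were in the table. The chromosome of the reference symbol could be compared for 138 members, and 6 on another chromosome were dropped, which left 234. Gene length could be compared for 130 members, of which 117 were within 1.5-fold of the reference. Members outside that range were kept where the chromosome agreed, and their names are uncertain. Of the genes named below, this concerns OsDREB2A, with 4822 bases implied by the FPKM values against 2044 in the reference. Names that could not be compared with a reference symbol rest on the fixed lists alone. Among them are OsNCED1, OsNCED5, Rab16A, OsbZIP10/ABI5, OsWRKY45, PsaN, PsaK, OsPR1b, OsJAZ11 and SDG725. OsDXS3 and OsDPF could not be compared either, and their names rest on further lists chosen after the data were seen. No coordinates are printed, since the builds may differ.

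The table holds 34119 genes, of which 2856 were at 0 in every library. In this table a gene's FPKM values are whole multiples of the value of 1 read, which gave whole reads for 29223 of 31263 genes (93.5%, tolerance 0.02 of a read) together with the implied library sizes and gene lengths. Reads summed over these genes were 1.07, 1.05 and 1.07 times the implied library size in the wild type and 0.995, 0.998 and 0.972 times in the overexpression line, so the FPKM denominators are not plain sums of reads in the table. In tests on simulated reads, 97.2% of genes were given reads and 98.8% of those were exact. The simulated genes were drawn from those already given whole reads, with their recovered lengths and library sizes. The test therefore does not cover the unresolved genes.

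The main test was limma (version 3.58.1, R 4.3.3) on log2(FPKM + 1), with moderated variances that follow a trend with expression, over genes with an FPKM of at least 1 in at least 3 of the 6 libraries, two-sided, with Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Gene lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 20 lists. Tested on simulated data over 18569 genes for this comparison, the fit recovered 6% of genes changed by 0.25 log2, 50% at 0.5, 94% at 1 and 100% at 2, and 4.6% of calls were unchanged genes. Of 200 random simulated lists, 7.5% had a camera p below 0.05. The simulation changed a far smaller share of genes than the 34.3% called in the real data. It also drew genes independently and gave both genotypes the same spread. These percentages therefore do not measure power or error in the real comparison. Precision is set by the 3 libraries per genotype and, for low genes, by depth: 1 read in a 1 kb gene was worth an FPKM between 0.0402 and 0.0752.

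Replicates were compared before averaging. Overexpression replicates 1 and 2 were the closest pair, with a variance 1.49 times that of sampling noise. The other overexpression pairs were at 1.93 and 1.95 times, and wild-type pairs ranged from 3.22 to 7.87 times. Relative to sampling noise, every overexpression pair was thus closer than any wild-type pair, while the main fit takes the same variance for both genotypes. The labels list replicates 1 and 2 as separate repeats and their values are not identical, so both were kept. A chi-square comparison against counting noise separated every pair of libraries, which repeat preparations of 1 RNA would also do, so it does not show that the closest pair came from separate plants. Counting that pair as 1 sample is an alternative, which would not cover a source shared by all 3 overexpression libraries.

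Named genes followed a rule fixed before the data were examined: SDG708, OsNCED3 and OsNCED5, members of each list with the smallest p, the strongest member against the direction of a list, and the largest other changes with complete separation of the groups and a mean FPKM of at least 5. Since no table names other loci, at most 2 such identifiers per direction are printed. LOC_Os04g34976 takes 1 of these places because of its number next to that fixed for SDG708, and the choice was made outside the rule, as was that of LOC_Os04g34984, the next number above.

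Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, the repeat number as a block, median-ratio scaling, quantile normalization, other variance models, leaving out each library, an estimated correlation or fry for lists, and the authors' p-values. Alternatives chosen after seeing the data were voom on the whole reads, array weights, overexpression replicates 1 and 2 as 1 sample, scaling to the reads in the table, and removal of a per-library trend on gene length. Further lists for the closing section were also chosen then.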

Results

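Polyadenylated RNA of rice seedlings was sequenced after a dehydration treatment, 3 h in a 20% solution of PEG8000, a polyethylene glycol that withdraws water from roots. The seedlings were 14 days old and belonged to the wild type (NIP) or to 1 line that overexpresses SDG708, a SET-domain protein, as a fusion to a yellow fluorescent protein. Each genotype had 3 repeats, and the wild-type repeats were each sequenced on 2 lanes, so that 9 samples gave 6 libraries. The FPKM values implied library sizes of 17.4, 24.9 and 20.0 M reads in the wild type and 13.3, 13.6 and 18.1 M in the overexpression line. Every library came from treated plants, so the comparison below asks how the genotypes differed under PEG and not how either responded to it. Lanes were labelled for the wild type alone, and the lane and the genotype therefore cannot be told apart. The labels do not say that repeats came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

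Under PEG, all 9 tested genes of diterpenoid phytoalexin synthesis and 4 of 5 pathogenesis-related genes rose in the overexpression line against the wild type, as did, by smaller folds, 25 of 26 tested genes of the photosynthetic apparatus. Of 9 genes for LEA proteins and dehydrins, which accumulate in water-stressed cells, 6 fell, as did 5 of 10 SnRK2 kinases of the abscisic acid (ABA) pathway. As lists, all of these passed with a preset correlation (camera), and with an estimated one the phytoalexin list alone did. The phytoalexin list had an adjusted p = 0.0449 with an estimated correlation, against 0.104 for pathogenesis-related genes, 0.183 for photosynthesis and 0.425 for both the LEA and the SnRK2 lists. Of 18569 genes tested, 2654 were higher and 3706 lower in the overexpression line (limma, Benjamini-Hochberg adjusted p below 0.05). Changes of at least 2-fold were mostly increases, with 297 genes higher and 62 lower. These counts were 517 and 128 with a pseudocount of 0.1 and 96 and 21 with a pseudocount of 5. Without 708OE_PEG replicate 3, 179 genes were at least 2-fold higher, and without NIP_PEG replicate 2, 100 were at least 2-fold lower. The 3 overexpression libraries lay all above or all below the 3 wild-type libraries for 50.6% of tested genes, against 10% by chance. The balance between higher and lower genes depended on scaling: with libraries scaled to the reads counted in the table, 3675 genes were higher and 2098 lower. With 708OE_PEG replicates 1 and 2, the closest pair, as 1 sample the number of called genes was 3893. Without 708OE_PEG replicate 3 it was 3378, without replicate 1 it was 3739, without replicate 2 it was 3782, and without NIP_PEG replicate 3 it was 4039.

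The locus number fixed beforehand for SDG708 itself was not among the genes of the table used, so the level of the overexpressed gene could not be read directly. The locus with the number just below it, LOC_Os04g34976 on chromosome 4, had an FPKM of 5.15 ± 0.665 (SD, n = 3) in the wild type and 149.9 ± 3.70 (SD, n = 3) in the overexpression line. Its log2 fold change was 4.62 with an SE of 0.08, and an exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 libraries against 3 allow. The locus with the number just above, LOC_Os04g34984, had an FPKM of 6.04 ± 0.862 and 5.03 ± 0.568 (SD, n = 3 each) and did not pass (log2 fold change -0.22, limma adjusted p = 0.15). The tables used here pair neither locus with the name SDG708.

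Members of the ABA synthesis list moved in both directions, but the only rise was that of OsNCED1, whose place in the list is uncertain. It was listed by name alone with the 9-cis-epoxycarotenoid dioxygenases, which catalyse the committed step of ABA synthesis. That name could not be compared with a reference symbol. OsNCED1 rose from an FPKM of 24.0 ± 2.68 to 90.3 ± 7.39 (SD, n = 3 each), a log2 fold change of 1.87 (SE 0.10, limma adjusted p = 1e-05). Its relative OsNCED5 fell from 4.37 ± 0.776 to 2.32 ± 0.197 (SD, n = 3 each; log2 fold change -0.68, SE 0.11, limma adjusted p = 0.0033). OsNCED3 was 59.2 ± 2.96 in the wild type and 50.1 ± 2.83 in the overexpression line (SD, n = 3 each), a log2 fold change of -0.24 (limma adjusted p = 0.033). That small change did not pass under median-ratio scaling (adjusted p = 0.055), after quantile normalization (0.066), with 708OE_PEG replicates 1 and 2 as 1 sample (0.074) or when libraries were scaled to the reads in the table (log2 fold change -0.13, adjusted p = 0.18). It was also lost without NIP_PEG replicate 2 (0.06) or 3 (0.11) and without 708OE_PEG replicate 1 (0.081), 2 (0.073) or 3 (0.13). Of the 7 tested synthesis genes 1 rose, 5 fell and 1 did not pass, with the same counts adjusted over the list alone. Along with that of OsNCED3, the falls of OsAO3 and OsABA1/ZEP were lost without NIP_PEG replicate 3 (limma adjusted p = 0.076 and 0.12). The same held without 708OE_PEG replicate 1 (0.069 and 0.11) or 3 (0.077 and 0.096). The list as a whole did not pass (camera adjusted p = 0.338). Among 3 genes of ABA breakdown, which encode ABA 8'-hydroxylases, OsABA8ox1 fell from 72.8 ± 2.70 to 37.4 ± 0.826 (SD, n = 3 each; log2 fold change -0.94, limma adjusted p = 3.2e-05), OsABA8ox3 rose by a log2 fold change of 0.39 (limma adjusted p = 0.014), and 1 did not pass. These counts were the same adjusted over the list alone, and the list did not pass (camera adjusted p = 0.75). The call of OsABA8ox3 was lost without NIP_PEG replicate 3 (adjusted p = 0.054), without 708OE_PEG replicate 1 (0.057) or 2 (0.054), and with these 2 replicates as 1 sample (0.052).

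In ABA signalling, 5 of 10 SnRK2 kinases (SAPK genes) fell and 5 did not pass, with the same counts adjusted over the list alone. SAPK1 had a log2 fold change of -0.49 (SE 0.07, limma adjusted p = 0.0021), SAPK6 of -0.47 (SE 0.09, adjusted p = 0.0052) and SAPK10 of -0.45 (SE 0.10, adjusted p = 0.01). The SAPK list passed with a preset correlation (camera adjusted p = 0.0223) and did not with an estimated one (adjusted p = 0.425 with an estimated correlation). It also did not pass after quantile normalization (adjusted p = 0.0642) or with a mean FPKM of at least 5 required (adjusted p = 0.101). Its median log2 fold change of -0.20 was -0.11 with the trend on gene length removed and also -0.11 with libraries scaled to the reads in the table. Of 6 ABA-responsive bZIP factors 3 fell, over all genes and adjusted over the list alone, and 3 did not pass. OsbZIP10/ABI5 showed the largest fall among them, from 10.8 ± 0.680 to 4.40 ± 0.202 (SD, n = 3 each; log2 fold change -1.13, limma adjusted p = 3.2e-05). The other falls, OsbZIP12 and OsbZIP66/TRAB1, were lost without 708OE_PEG replicate 1 (limma adjusted p = 0.054 and 0.051), 2 (0.052 and 0.087) or 3 (0.072 and 0.12). The bZIP list missed the threshold (camera adjusted p = 0.109), and passed without a filter on low genes (adjusted p = 0.0373). Of 9 clade A protein phosphatases 2C, which restrain these kinases, 2 fell and 7 did not pass (camera adjusted p = 0.577). Both falls, OsPP2C06 and OsPP2C50, were lost without 708OE_PEG replicate 1 (limma adjusted p = 0.058 and 0.074) or 3 (0.08 and 0.091). They were also lost with 708OE_PEG replicates 1 and 2 as 1 sample (0.052 and 0.059). Of 6 tested ABA receptors 1 rose and 5 did not pass (camera adjusted p = 0.428). The counts of phosphatases and of receptors were the same adjusted over the list alone.

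Among LEA and dehydrin genes, OsLEA3-1 fell from 1788 ± 152 to 939.9 ± 49.9 (SD, n = 3 each; log2 fold change -0.93, SE 0.09, limma adjusted p = 0.00031), and Rab16A had a log2 fold change of -0.60 (SE 0.13, adjusted p = 0.0085), a call lost after quantile normalization (log2 fold change -0.25, adjusted p = 0.067) and without a filter on low genes (adjusted p = 0.057). Of 9 members 6 fell and 3 did not pass, and 8 fell adjusted over the list alone. The list passed with a preset correlation (camera adjusted p = 0.00871) and not with an estimated one (adjusted p = 0.425 with an estimated correlation), nor with a mean FPKM of at least 5 required (adjusted p = 0.0644). Photosynthesis transcripts moved the opposite way in the same libraries.

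Of 17 tested transcription factors linked to drought and cold, 4 rose, 8 fell and 5 did not pass, and 9 fell with 4 rising adjusted over the list alone. OsDREB1C had a log2 fold change of -0.69 (SE 0.08, limma adjusted p = 0.00073), OsNAC5 of -0.41 (SE 0.06, adjusted p = 0.0018) and OsDREB2A of -0.67 (SE 0.10, adjusted p = 0.0019). The name OsDREB2A is uncertain for this locus, since its length in the table was 2.36 times that of the reference gene of that name. OsWRKY45, a regulator of defence, rose from 8.86 ± 0.273 to 22.7 ± 2.23 (SD, n = 3 each; log2 fold change 1.26, limma adjusted p = 3.2e-05). The list did not pass (camera adjusted p = 0.361). Of 9 genes for proline, trehalose, raffinose and betaine synthesis 3 fell and 6 did not pass, and 4 fell with 1 rising adjusted over the list alone (camera adjusted p = 0.577). OsBADH1, a betaine aldehyde dehydrogenase, had a log2 fold change of -0.32 (limma adjusted p = 0.0064). The other falls, OsP5CS2 and OsP5CS1, were lost without NIP_PEG replicate 3 (limma adjusted p = 0.068 and 0.14) and without any 1 of the 708OE_PEG replicates (0.067 to 0.15). Of 11 antioxidant enzymes 3 rose, 2 fell and 6 did not pass, and 4 rose with 2 falling adjusted over the list alone (camera adjusted p = 0.338). The catalase gene CatA had a log2 fold change of 0.38 (limma adjusted p = 0.011), which just missed the threshold without 708OE_PEG replicate 2 (adjusted p = 0.05). Of 12 tested aquaporins 2 rose, 2 fell and 8 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.338). Both rises were lost without 708OE_PEG replicate 2 (limma adjusted p = 0.06 and 0.11), and both falls without NIP_PEG replicate 3 (0.055 and 0.089).

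**Figure D1:**
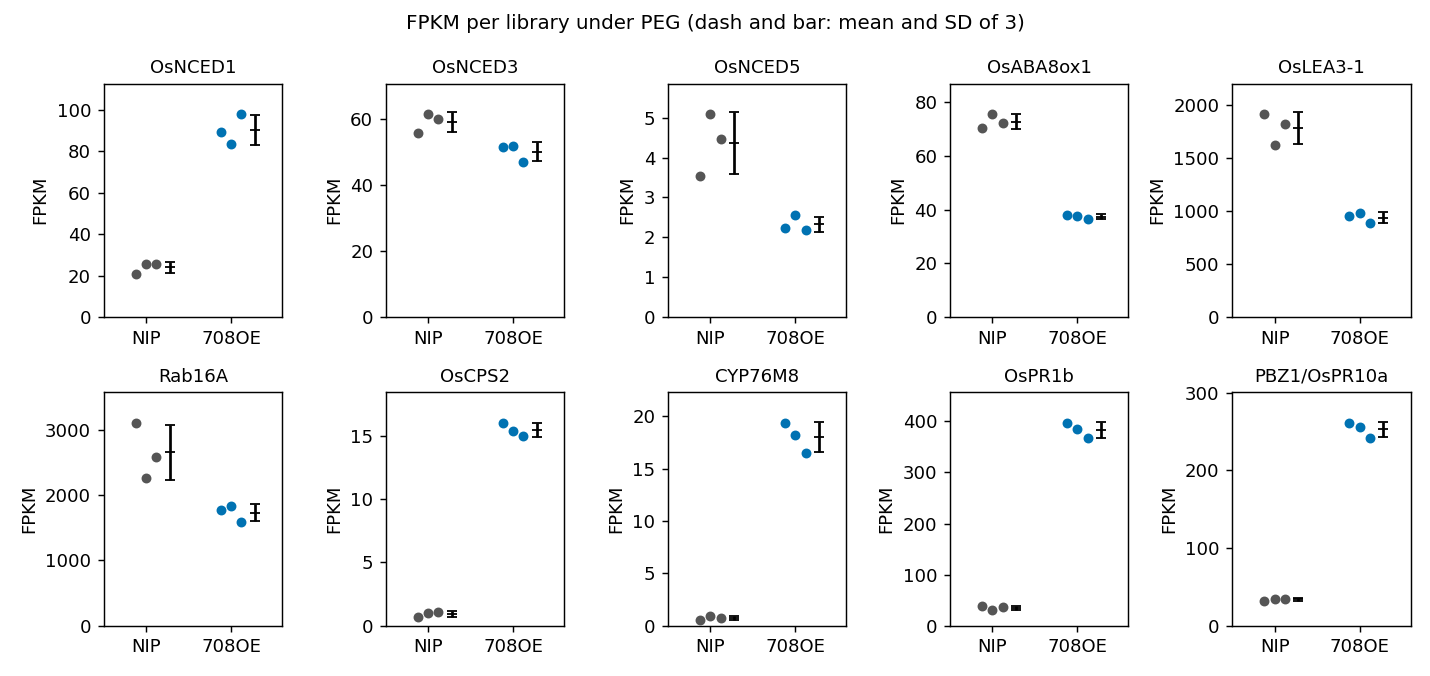
FPKM of 10 genes under PEG on linear axes from 0, with 1 point per library, 3 wild-type (NIP) and 3 overexpression (708OE) libraries per gene, and a dash with a bar for the mean and SD of the 3. OsPR1b lies at 34.8 in the wild type and 383 in the overexpression line, and OsLEA3-1 at 1788 and 939.9.

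Transcripts of the photosynthetic apparatus were higher in the overexpression line almost throughout. Of 26 tested members 25 rose and 1 did not pass, and 26 rose adjusted over the list alone. The median log2 fold change was 0.72, with a range from 0.26 to 1.39. PsaN, a subunit of photosystem I, rose from 172 ± 5.72 to 342 ± 33.4 (SD, n = 3 each; log2 fold change 0.98, SE 0.08, limma adjusted p = 0.00015), and PsaK had a log2 fold change of 0.74 (SE 0.07, adjusted p = 0.00026). The list passed with a preset correlation (camera adjusted p = 2.54e-17) and not with an estimated one (adjusted p = 0.183 with an estimated correlation). These genes are markers of green shoot tissue, and whole seedlings hold shoots and roots. Of 13 root markers used, 11 had a mean FPKM under 1 in the wild type, and the highest was Lsi1, a silicon transporter, at 2.83. The 2 that reached the level needed for testing did not pass, so no test of the root list was made. Of 4 stomatal lineage markers 1 was tested and did not pass. Of 5 tested markers of dividing cells 1, PCNA, rose (log2 fold change 0.41, limma adjusted p = 0.0091) and 4 did not pass (camera adjusted p = 0.818), with a median log2 fold change of -0.06, a mean of 0.02 and a test in the upward direction. The 4 markers of secondary walls and vascular tissue did not pass (camera adjusted p = 0.946). Counts for these marker lists were the same adjusted over the list alone.

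The steepest rises among the fixed lists were in defence genes. All 9 genes of diterpenoid phytoalexin synthesis, the pathway to antimicrobial compounds of rice, rose over all genes and adjusted over the list alone, with a median log2 fold change of 2.59 and a range from 1.18 to 3.46. The median depended on how low values were treated and was 3.92 with voom on whole reads. With a pseudocount of 5 the log2 fold changes of OsCPS2 and CYP76M8, both described next, were 1.79 and 2.01. OsCPS2, a diterpene cyclase at the head of the pathway, went from an FPKM of 0.930 ± 0.21 to 15.5 ± 0.534 (SD, n = 3 each; log2 fold change 3.10, SE 0.09, limma adjusted p = 4.4e-07). The cytochrome P450 gene CYP76M8 went from 0.732 ± 0.184 to 18.0 ± 1.43 (SD, n = 3 each; log2 fold change 3.46, SE 0.10, limma adjusted p = 3.5e-07). The list passed with a preset correlation (camera adjusted p = 2.09e-14) and with an estimated one (adjusted p = 0.0449 with an estimated correlation). Several members are neighbouring paralogs between which reads may be split, so single values are uncertain.

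Of 5 pathogenesis-related genes 4 rose and 1 fell, with the same counts adjusted over the list alone. OsPR1b rose from 34.8 ± 3.27 to 383 ± 15.0 (SD, n = 3 each; log2 fold change 3.43, SE 0.08, limma adjusted p = 1.5e-07). PBZ1/OsPR10a had a log2 fold change of 2.87 (SE 0.07, adjusted p = 1.5e-07), and JIOsPR10, a member named for its induction by jasmonate, of -0.40 (SE 0.07, adjusted p = 0.0052). The list passed with a preset correlation (camera adjusted p = 4.27e-05) and not with an estimated one (adjusted p = 0.104 with an estimated correlation). Of 12 genes of jasmonate synthesis and JAZ repressors 3 rose, 6 fell and 3 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.364). Of those that fell, 5 were JAZ repressors, led by OsJAZ11, which went from 95.2 ± 2.09 to 53.6 ± 1.03 (SD, n = 3 each; log2 fold change -0.82, limma adjusted p = 5.7e-05).

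**Figure D2:**
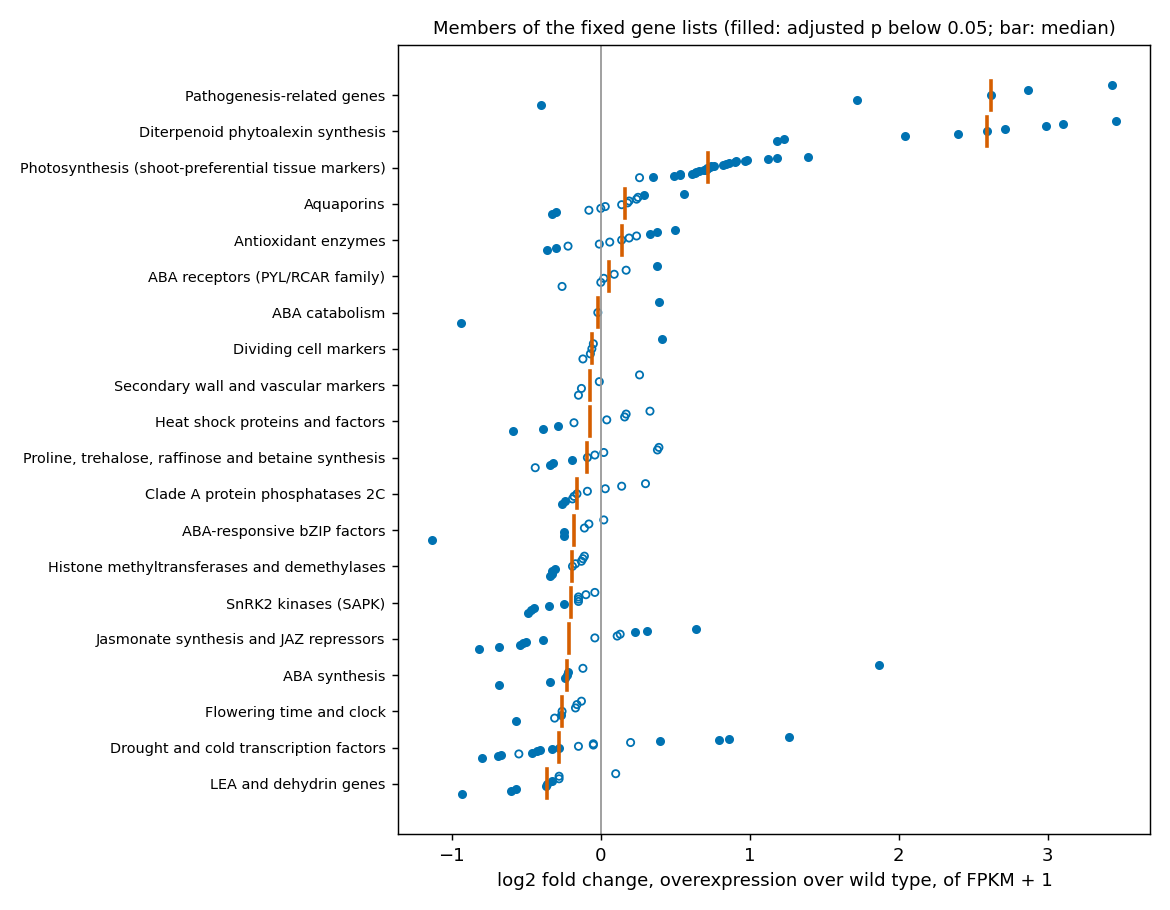
Log2 fold change of each tested member of the 20 fixed lists with at least 3 tested genes, on the scale of FPKM + 1, with 1 point per gene, filled where the adjusted p was below 0.05, and a bar at the list median. The medians of the diterpenoid phytoalexin and pathogenesis-related lists lie at 2.59 and 2.62 (3.92 and 2.66 with voom on whole reads), and that of photosynthesis at 0.72.

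Of 9 tested histone methyltransferases and demethylases 4 fell and 5 did not pass, and 5 fell adjusted over the list alone. JMJ703, a histone demethylase, had a log2 fold change of -0.31 (SE 0.06, limma adjusted p = 0.0075) and the methyltransferase SDG725 of -0.34 (SE 0.08, adjusted p = 0.017). SDG725 lost its call without NIP_PEG replicate 3 (0.061) and without 708OE_PEG replicate 1 (0.063), 2 (0.057) or 3 (0.052). It also lost the call with 708OE_PEG replicates 1 and 2 as 1 sample (0.056) and with the trend on gene length removed (log2 fold change -0.21, adjusted p = 0.076), as did JMJ703 with that trend removed (log2 fold change -0.18, adjusted p = 0.055). The other falls, JMJ706 and SDG718, were lost without NIP_PEG replicate 3 (limma adjusted p = 0.076 and 0.064) and without any 1 of the 708OE_PEG replicates (0.066 to 0.089). With the trend on gene length removed they were lost as well (0.078 and 0.11), so none of the 4 falls kept its call there. The list passed with a preset correlation (camera adjusted p = 0.0335) and not with an estimated one (adjusted p = 0.554 with an estimated correlation). It did not pass without NIP_PEG replicate 1 (adjusted p = 0.0884), without 708OE_PEG replicate 1 (adjusted p = 0.0646), with 708OE_PEG replicates 1 and 2 as 1 sample (adjusted p = 0.0509), with the trend on gene length removed (adjusted p = 0.253) or with a mean FPKM of at least 5 required (adjusted p = 0.209). Its median log2 fold change of -0.19 was -0.06 with that trend removed and -0.12 with libraries scaled to the reads in the table. Of 7 tested flowering and clock genes 2 fell and 5 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0864), and the list passed without NIP_PEG replicate 2 (adjusted p = 0.0402). Hd1, a regulator of flowering by day length, was 1 of them (log2 fold change -0.57, limma adjusted p = 0.0076). Of 8 tested heat shock proteins and factors 3 fell and 5 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.614). The falls of a small heat shock protein and of OsHsfA2a were lost without 708OE_PEG replicate 2 (limma adjusted p = 0.067 and 0.12) or 3 (0.075 and 0.1).

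Outside the lists, LOC_Os11g40530 on chromosome 11 had the largest rise under the fixed rule. It had 0 reads in the 3 wild-type libraries and FPKM values of 45.1, 41.6 and 35.9 in the overexpression libraries, at least 444-fold higher against a floor of 3 reads over the wild-type group. That bound takes the overexpression level as measured, and the exact binomial 95% interval of the ratio of pooled reads starts at 361. Both cover counting error only. The largest falls were less even. LOC_Os01g57968 on chromosome 1 had FPKM values of 301, 129 and 275 in the wild type and 0.341, 76.3 and 1.69 in the overexpression line (limma adjusted p = 0.019), and lost its call without 708OE_PEG replicate 1 (adjusted p = 0.055), without 708OE_PEG replicate 3 (0.074) and without NIP_PEG replicate 3 (0.061). It also lost the call with a robust variance model (0.076) and without a filter on low genes (0.058), and the p-value in the authors' deposited table was 0.117. LOC_Os10g21192 on chromosome 10 had values of 109.6, 11.2 and 142 against 5.88, 3.53 and 2.91 (limma adjusted p = 0.012), and lost its call without 708OE_PEG replicate 3 (adjusted p = 0.051) and with voom on whole reads (0.053).

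In the authors' deposited table, p-values adjusted here gave 9022 genes, 3960 higher and 5062 lower in the overexpression line. Of these, 68.3% were also called here with the same sign (exact binomial 95% interval 67.4 to 69.3). That interval takes genes as independent, which they are not, so it understates the uncertainty. Leaving out each library in turn gave shares from 36.7% to 71.6%. Only 7975 of the 9022 genes were among the genes tested here, and of those 77.3% (6164) were called here with the same sign. In the other direction, 96.9% of the genes called here were in the set from the authors' deposited table with the same sign. Both come from the same libraries and are not independent.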

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

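Voom, array weights, the merged overexpression replicates, scaling to the reads in the table and removal of the length trend were chosen after seeing the data. Of 68 genes that the naming rule took and that passed, 35 were called with the same sign under all 20 alternatives of the fit, 6 were called wherever tested but untested under at least 1, and 27 lost the call under at least 1, without a change of sign. Log2 fold changes moved by over 1.5 times for 19 of them with a pseudocount of 5 (OsNCED5 -0.35, OsABA8ox3 0.20, SAPK10 -0.27, OsbZIP10/ABI5 -0.75, Hd1 -0.36, SDG725 -0.20, PCNA 0.19), for 10 with scaling to the reads in the table and for 10 without the length trend. The diterpenoid phytoalexin, pathogenesis-related and photosynthesis lists passed under these 20 alternatives, and the SAPK, LEA and histone lists each lost the call under at least 1. The SDG708 locus gave no value under any setting. Count tests planned for a table of counts were not run. Array weights stopped short of their convergence tolerance.

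The number of genes at least 2-fold changed depended on the pseudocount by construction. It was 645 (517 higher, 128 lower) with 0.1, 117 (96 higher, 21 lower) with 5, 674 (546 higher, 128 lower) with voom on whole reads and 1452 (1146 higher, 306 lower) in the authors' deposited table. With a mean FPKM of at least 5, fewer genes were tested, and 1592 were higher, 186 changed by at least 2-fold (146 higher, 40 lower) and 3 lists passed. With 708OE_PEG replicates 1 and 2 as 1 sample, which leaves fewer samples, 3893 genes were called, 1642 higher and 2251 lower. With libraries scaled to the reads in the table, 2098 genes were lower. With an estimated correlation 1 list passed, and fry, which does not compare a list with other genes, passed 13.

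Leaving out each library in turn gave 3378 to 7148 called genes, 1494 to 3086 higher and 1884 to 4062 lower, 224 to 455 changed by at least 2-fold (179 to 355 higher, 45 to 100 lower, the latter without NIP_PEG replicate 2), and 36.7% to 71.6% of the authors' calls shared. That share, 68.3% in the main fit, was 58.4% without a filter, 51.1% with a mean FPKM of at least 5, 64.3% with median-ratio scaling, 63.5% with quantile normalization, 66.5% without a variance trend, 72.8% with voom, 81.0% with array weights, 42.5% with the merged replicates, 56.9% with scaling to the reads in the table and 56.3% without the length trend. The cause of these shifts was not tested.

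Some lists that did not pass changed the direction of the camera test and stayed above the threshold. These were ABA synthesis (adjusted p = 0.823 with a mean FPKM of at least 5), dividing cells (0.894, quantile normalization) and secondary walls (0.839 with a mean FPKM of at least 5, 0.952 median-ratio, 0.744 quantile, 0.954 array weights, 0.769 scaled to the reads in the table, 0.728 without the length trend, and 0.812 to 0.98 over the fits without 1 library, where 2 of the 6 changed direction).

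With the repeat number as a replicate block 5619 genes were called (2493 higher, 3126 lower), 365 by at least 2-fold, 7 of the 68 genes, OsNCED3 (adjusted p = 0.065) among them, did not pass, 6 lists passed and 60.1% of the authors' calls were shared. Deviations of libraries with the same number did not go together (correlations across genes of -0.005, -0.002 and -0.045), so the numbers do not pair the libraries.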

Other observations

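The tests of variation between wild-type libraries, of shared reads, of the share of root RNA, of the line or batch, of a length-dependent difference between preparations and of clustering along chromosomes were chosen only after the results were seen, as were the 6 further gene lists. The comparison of splits, the effect of the length trend on the LEA and photosynthesis lists and the test without list members were set out before their results.

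Of genes around the phytoalexin pathway, most in the plastid precursor and further diterpenoid lists also rose in the overexpression line, unlike most gibberellin genes. In the plastid isoprenoid precursor pathway, which feeds diterpenoid synthesis, 6 of 8 genes rose, 0 fell and 2 did not pass, and 7 rose adjusted over the list alone. OsDXS3 rose from an FPKM of 1.41 ± 0.303 to 20.9 ± 0.807 (SD, n = 3 each; log2 fold change 3.19, limma adjusted p = 5.3e-07), while its relative OsDXS2 was 9.68 ± 0.480 and 9.04 ± 0.358 (log2 fold change -0.09, limma adjusted p = 0.34). The list passed with a preset correlation (camera adjusted p = 2.52e-05) and not with an estimated one (adjusted p = 0.131 with an estimated correlation). All 6 tested further diterpenoid genes rose, among them OsDPF, a bHLH regulator of phytoalexin genes (0.435 ± 0.172 to 5.13 ± 0.541, SD, n = 3 each; log2 fold change 2.1, limma adjusted p = 1.2e-05), with a camera adjusted p = 2.61e-08 and an adjusted p = 0.0705 with an estimated correlation. Of 7 tested gibberellin genes, which use the same precursor, 1 rose, 1 fell and 5 did not pass (camera adjusted p = 0.818).

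Of 12 WRKY factors linked to defence 4 rose, 4 fell and 4 did not pass, with a median log2 fold change of -0.12, a mean of 0.16 and a camera adjusted p = 0.761. OsWRKY62 had a log2 fold change of 1.39 (limma adjusted p = 0.00029) and OsWRKY72 of -0.55 (adjusted p = 0.0094). Of 9 tested genes at the entry to phenylpropanoids 4 rose and 5 did not pass (camera adjusted p = 0.00365, and adjusted p = 0.133 with an estimated correlation). Of 10 genes of chlorophyll synthesis 8 rose and 2 did not pass (camera adjusted p = 1.15e-06, and adjusted p = 0.131 with an estimated correlation), among them PORA and PORB with log2 fold changes of 1.16 and 1.08 (limma adjusted p = 9.7e-05 and 6.4e-05).

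The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 6360 genes and 359 genes of at least 2-fold, and the highest of the other splits called 0 of each, so that 1 of the 10 splits gave as many. For the fixed lists 2 of the 10 splits gave as many as the real 6, since another split, which set NIP_PEG replicates 1 and 3 with 708OE_PEG replicate 2 against the rest, also called 6. The preset-correlation test thus called lists in splits in which no single gene passed. Each of these other splits mixed both genotypes on both sides. Part of the genotype difference therefore stayed between the sides, and the rest widened the spread within them. Few gene calls were likely there from the outset, and lists called there may carry the genotype difference. These splits thus measure neither false list calls nor the strength of the gene counts.

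The rise of phytoalexin and pathogenesis-related genes was weighed first. Differences between 2 wild-type libraries correlated across genes with that between overexpression and the remaining one at Pearson's r = 0.327 (replicate 2 minus 1), 0.068 (3 minus 1) and -0.367 (3 minus 2), genes not being independent replicates. On the first principal component of all genes outside the 4 lists weighed here, the wild-type range was 0.37 of the difference between genotypes. For the means of the phytoalexin and pathogenesis-related lists it was at most 0.05. This argues, within limits, against a state that varies among these wild-type libraries as the whole cause. The comparison with that component replaced an earlier bound after these values were seen. Lists weighed for a steep rise also tend to give a small share. For phytoalexin genes, low in the wild type, the scale of FPKM + 1 further narrows the wild-type range. The lowest median log2 fold change among phytoalexin genes of chromosome 2, those of chromosome 4 and pathogenesis-related genes of chromosomes 1, 7 and 12 was 2.04. JIOsPR10, which fell (-0.40), lies on chromosome 3 and was in none of these groups. The groups were set after the values were seen, when no phytoalexin member lay below 1.18, so a high median was known beforehand. The values show only that the rise was not confined to 1 of these groups, and sharing of reads within each group stays open. An effect of SDG708 may account for the rise, but with 1 overexpression line and lanes labelled for the wild type alone, it cannot be told apart from a property of this 1 line or of its library batch.

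The fall of LEA genes and the rise of photosynthesis genes were smaller. With the per-library trend on gene length removed, the median log2 fold changes were 1.25 and 0.92 times their value, which argues against that trend as the whole cause. If fewer roots alone gave the photosynthesis rise, roots would supply at least 39.4% of wild-type RNA, and the 13 root markers, with a median wild-type FPKM of 0.0557, would then have a median of 0.141 in pure root, which argues against it. The line, its batch, the overexpression itself and other tissue proportions stay open. Roots stay open for the LEA genes, since transcripts found mainly in roots fall with a root share of any size. The LEA level that pure root would then need was not worked out. A state that varies among wild-type libraries also stays open. Their range of list means was 0.28 of the difference for LEA genes and 0.22 for photosynthesis, not far below the 0.37 of that component.

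Longer genes were lower in the overexpression line. Spearman's rho between gene length and log2 fold change was -0.257 across genes, with a median log2 fold change of 0.10 in the shortest sixth (734 genes higher, 386 lower) and -0.13 in the longest (203 higher, 935 lower). A length-dependent difference between library preparations may contribute, since a trend of similar size lay between NIP_PEG replicates 2 and 3 (rho 0.188) and between replicates 1 and 2 (rho -0.172), while differences among overexpression libraries had a rho of at most 0.037. Without the trend 2785 genes were higher and 2689 lower.

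Rising genes also lay next to each other. Among tested genes in order of locus number, 34 neighbouring pairs both rose at least 2-fold, against at most 16 in 10000 shuffles within chromosomes (permutation p = 1e-04, the smallest they can give), and 9 pairs both fell, against at most 4. The listed genes of the diterpenoid clusters did not account for this alone, since with members of all lists left out 21 pairs remained, against at most 13 in shuffles (permutation p = 1e-04). Runs of rising genes at these clusters also held loci on no list, which were not left out. Part of the 21 pairs may therefore still come from the clusters. Tandem copies that share reads or regulation may underlie such pairs, which these data do not separate.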
